A study of Mus musculus with 11 samples.

How the data were processed

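RNA-seq libraries of mouse ESCs and EBs, WT and Mettl3 KO, were analysed, with 3 libraries in each ESC group and 2 in each EB group. The series also names 1 WT embryonic fibroblast library, which is not analysed here. Per the labels, poly(A) RNA was sequenced, the libraries were made with a TruSeq RNA kit, which does not keep the strand, and ESC replicate C was measured alongside a SILAC protein assay. Counts of the noncoding RNA Rn7sk outside ESC replicate C (given below) do not bear out the poly(A) label. The submitters' processing notes name CASAVA 1.8.2, Bowtie, TopHat2 2.0.10, HTSeq 0.6.0, DESeq and the genome build mm10, without the annotation release, the strand setting or filters.

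The deposited table holds normalized signal, namely gene read counts that the authors divided by one DESeq size factor per library. Dividing each column by its smallest value above 0 gave whole numbers within a tolerance of 0.01 for 100% of values, so whole reads were recovered. Of 39179 gene identifiers, 37607 had a symbol in the GENCODE reference for GRCm38, and 5 summary lines of the counting program were left out. Symbols, coordinates and gene types come from that reference. Reads assigned to genes ranged from 3026837 to 15426894 per library. Reads in no gene made up 34.0% to 38.8% of records, and alignments that were not unique 28.7% to 30.6% in ESC replicate C and 36.9% to 46.1% in the other libraries.

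The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Values plus a pseudocount of 1 were put on the log2 scale, and 15781 genes with a mean of 10 or more over the 10 libraries were tested. One limma 3.58.1 fit with 4 group means and trended, robust variances gave 5 contrasts (KO against WT in ESCs and in EBs, EBs against ESCs in WT and in KO, and the difference of the KO effects). Tests are two-sided, with Benjamini-Hochberg adjustment over genes within a contrast and a threshold of 0.05. The fit has 6 residual degrees of freedom, and 3 with a replicate block. EB groups of 2 borrow their spread from all 4 groups. P values measure the spread between the libraries as labelled. In the main fit this includes, for the EB contrasts too, the spread between ESC replicate C and A and B. For H19, Meg3 and Rian, chosen after their values were seen, the SE in KO against WT EBs was 1.01, 0.78 and 0.97. Without the replicate C libraries it was 0.13, 0.09 and 0.10. Group values are means with SD, and log2 differences have the SE of the fit.

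From textbook knowledge 25 gene lists were fixed, of which 24 had the 5 or more tested members needed for limma's camera test, run with a preset correlation of 0.01 and again with an estimated one, and adjusted over lists within a contrast. With an estimated correlation and no block, only the endoderm list passed, in KO against WT EBs, in WT EBs against ESCs and in the difference of KO effects. Beside each list with a preset adjusted p under 0.05, the adjusted p with the estimated correlation is given. Named genes were, per contrast and direction, the 8 with the largest change among those with an adjusted p under 0.05. They also needed a mean of 100 or more in the higher group, complete separation of the libraries (not asked of the difference of effects) and a name that is not a model name. Up to 4 called members per list and direction, the most abundant member that did not pass, and Mettl3 were added. Others are marked as chosen after their values were seen. Where a group had no read, a fold is a lower bound with 3 reads over the group as the floor, and with 1 to 3 reads the exact binomial 95% interval of the ratio is given.

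Letters A, B and C are shared by WT and KO. Deviations from the group mean had r = 0.845, 0.828 and 0.858 across genes between WT and KO ESCs of the same letter, above the bound of 0.1, so by the rule set in advance the ESC letters pair the libraries. Different letters gave 0.809 and 0.812 between A and B, and -0.836 to -0.846 between C and either, so the pairing rests mostly on C standing apart. Values with the letter as a block therefore stand beside the main ones. EBs had r = 0.369, with too few pairs to decide. The block nevertheless has a term for the EB letters too.

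The fit was tested on simulated data with 100 genes changed at each size. Where replicate C behaved like A and B, 93% of changes of 1 on the log2 scale were recovered in ESCs and 82% in EBs, with 5 and 1 false calls. Where replicate C was given the mean observed shift, the same in WT and KO, 11% and 1% were recovered with no false call. Changes of 2 were then recovered at 34% and 24%. With the block these shares were 72% and 62% for changes of 1, and 84% and 77% for changes of 2. No list of 20 without changes was called. Simulated genes varied independently and these lists were drawn at random, so this does not test lists whose genes vary together. The simulation gave every pair the same KO effect and both genotypes the same shift. In the data, KO effects of the C pair had r = 0.232 and 0.227 across genes with those of A and B. The shares and false calls therefore do not cover differences between lines.

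Alternatives were pseudocounts of 0.25 and 8, no filter and a mean of 50 or more, recomputed size factors, quantile normalization, the replicate block, only the groups of a contrast, eBayes without trend or robust variances, each library left out in turn, both replicate C libraries left out, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, and the estimated correlation. Leaving out genes of chromosomes 10, 11, X and Y, combining the block with leaving out replicate C, and combining either with the estimated correlation, were chosen after seeing the data. Reads of overlapping genes on opposite strands cannot be parted. Over 64 genes with 90% or more of their exons inside exons on the other strand, the read density relative to the overlapping gene had a median of 0.13 on the log2 scale (quartiles -1.14 and 0.87), so values of antisense genes are uncertain. Chromosome medians use protein-coding genes with a mean of 100 or more. Tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.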

Results

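Transcript levels were measured by RNA-seq in mouse cells with an intact Mettl3 gene (WT) and in Mettl3 knockout (KO) cells. Mettl3 is the catalytic subunit of the complex that writes N6-methyladenosine on messenger RNA. Embryonic stem cells (ESCs) had 3 libraries per genotype, labelled A, B and C. Embryoid bodies (EBs), aggregates in which ESCs differentiate, had 2 libraries per genotype, labelled A and B. The labels call these biological replicates, and say that ESC replicate C was measured alongside a protein assay by SILAC. ESCs were kept in serum-free medium with LIF, a GSK3 inhibitor and a MEK inhibitor, and EBs were grown without attachment in medium with serum for 8 to 21 days. The deposited values are DESeq-normalized counts, and whole read counts were recovered from them.

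Reads assigned to genes came to 3026837 and 3075007 in the replicate C libraries of WT and KO ESCs. The other 8 libraries held 8523027 to 15426894. Between 15934 and 16663 genes had a read in the replicate C libraries, against 22399 to 25852 elsewhere. A floor of 3 reads in 1 library stood at 8.33 to 9.88 normalized counts in replicate C and at 1.63 to 2.72 in the others. Counting error and PCR duplicates were not separated, so floors and intervals cover counting error only.

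The replicate C libraries stood apart from A and B of their own group. Across genes, log2 values of A and B had r = 0.990 in both WT and KO ESCs, while C reached r = 0.684 and 0.692 with A and B in WT and 0.653 and 0.659 in KO. Genes are not independent replicates. The first principal component held 69.6% of the variance and parted the replicate C libraries from all others. Histone genes, whose main transcripts carry no poly(A) tail, had a median of -7.47 or lower on the log2 scale in C relative to A and B in WT and -6.91 or lower in KO (54 genes). This sets genes under 3 reads in C at 3 reads, since 35 and 38 of them had no read there, and with the pseudocount alone the medians were -9.65 and -9.63. ERK targets, a list of genes induced by MEK and ERK signalling, were at 1.74 in WT and 1.87 in KO by the same measure (15 genes). Genes of collagen and other matrix proteins in the fibroblast and matrix list were at -3.36 and -2.67 (22 genes), or -1.52 and -2.48 with genes under 3 reads in C at 3 reads. Hox genes were at -2.83 and -2.30 (10 genes), or -1.03 and -1.51 at that floor. Chosen after its values were seen, the collagen gene Col3a1 had 3115 and 3171 normalized counts in A and B of WT ESCs and 6222 and 6532 in KO. It had 23.1 and 19.4 in C of WT and KO, and means of 1467 and 744 in WT and KO EBs. Col1a1 and Col1a2 were likewise higher in ESC replicates A and B than in the EBs. Whether A and B held cells other than ESCs was not tested.

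Mettl3 (ENSMUSG00000022160, chromosome 14, 52294840 to 52305130, minus strand, GRCm38) was lower in every KO library than in every WT library. WT ESCs held 422, 392 and 425 normalized counts and KO ESCs 138, 134 and 131. In WT EBs the counts were 399 and 368, and in KO EBs 154 and 147. The log2 difference was -1.62 in ESCs (SE 0.14, adjusted p = 0.0123) and -1.34 in EBs (SE 0.17, adjusted p = 0.0143). Of the Mettl3 exons, 18.4% overlap Tox4 on the other strand, and the libraries do not keep the strand, so part of the KO counts is uncertain. The other genes of the m6A machinery list, which holds writers, erasers and readers of the mark, moved both ways. Ythdf2, a cytoplasmic reader, rose by 1.36 on the log2 scale (SE 0.14, adjusted p = 0.0176) in KO ESCs, from 897 ± 85.3 to 2301 ± 253 normalized counts (SD, n = 3). The nuclear reader Ythdc1 rose by 1.18 on the log2 scale (SE 0.14, adjusted p = 0.0193) in the same comparison. In EBs, Ythdf2 rose by 0.99 (adjusted p = 0.0384) and Ythdc1 by 1.04 (adjusted p = 0.0306). The RNA-binding protein Igf2bp3, with 18.7% of its exons over Malsu1 on the other strand, fell by 1.49 in KO ESCs (adjusted p = 0.0303). Its relative Igf2bp1 fell by 1.06 in KO EBs (adjusted p = 0.0306). Igf2bp1 lies on chromosome 11, whose genes had a lower median in KO than in WT (given with the chromosomes). Of 20 list members tested, 2 rose and 2 fell in ESCs (4 rose and 2 fell adjusted over the list alone), and 2 rose and 2 fell in EBs (3 rose and 3 fell adjusted over the list alone). Mettl3 itself is among those that fell in each. The list as a whole did not pass, with adjusted p = 0.561 and 0.801.

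**Figure D1:**
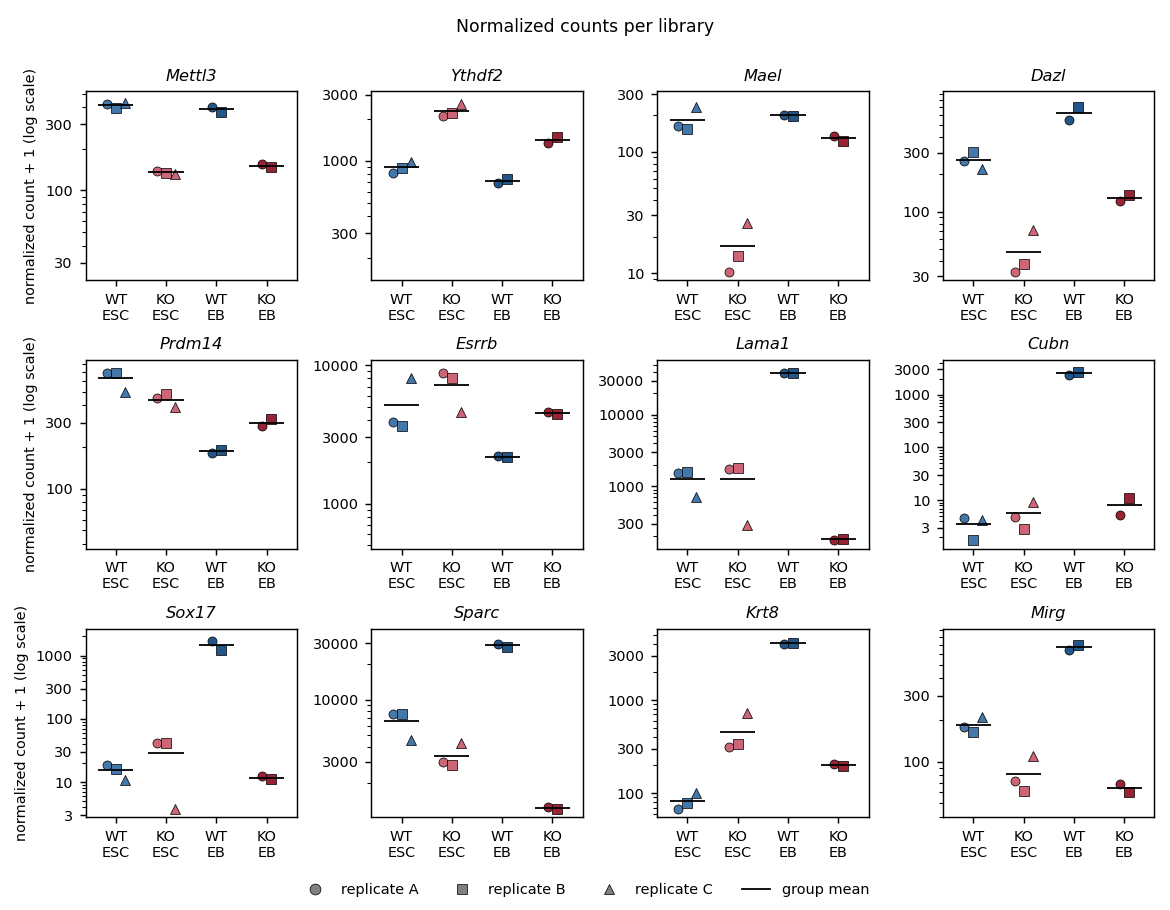
Normalized counts plus 1 (log axis) of 12 genes in each of the 10 libraries, with a point per library, shaped by replicate letter, and a bar at each group mean. Mettl3 was at 131 to 138 in KO ESCs against 392 to 425 in WT ESCs, and Lama1 had a mean of 38107 in WT EBs against 181 in KO EBs.

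The comparison of KO with WT ESCs asks which transcripts change with loss of Mettl3 under conditions meant to keep the cells undifferentiated. Replicates A and B held high Col3a1 counts (given above), so whether all their cells were undifferentiated is uncertain. Among germline genes the 3 called were lower. Dazl (ENSMUSG00000010592, chromosome 17, 50279400 to 50293640, minus strand), an RNA-binding protein of germ cells, went from 259 ± 41.8 to 45.8 ± 20.6 normalized counts (SD, n = 3) and fell by 2.55 on the log2 scale (SE 0.32, adjusted p = 0.0193). Mael (ENSMUSG00000040629, chromosome 1, 166201200 to 166238700, minus strand), which acts in piRNA silencing, fell by 3.56 (adjusted p = 0.0176), and Hormad1, a meiotic chromosome axis protein, by 2.29 (adjusted p = 0.0193). Of 17 germline genes tested, 0 rose and 3 fell, and 1 rose and 7 fell adjusted over the list alone, with a list median of -0.88 (adjusted p = 0.00109, 0.485 as the adjusted p with an estimated correlation).

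Genes outside the germline list also moved. The transmembrane protein gene Parm1 (ENSMUSG00000034981, chromosome 5, 91517620 to 91626890, plus strand) rose from 8.65 ± 3.1 to 264 ± 151 normalized counts, by 4.58 on the log2 scale (SE 0.56, adjusted p = 0.0193). Further rises were 4.44 for Cadps2, which primes vesicles for exocytosis, 3.28 for Tmem266, 3.25 for Plcl2, 3.21 for Pof1b, 3.06 for the zinc finger gene Tshz1 and 2.91 for Epdr1. Rpl10l stood at 2.92, but it is an intronless copy of Rpl10, and reads shared between such copies leave its value uncertain. The noncoding RNA Platr3 fell by 5.09 (SE 0.77, adjusted p = 0.0294), Islr2 by 3.78, Ndrg2 by 3.64, the citrate transporter Slc13a5 by 3.46, Crtac1 by 3.20 and Pnma5 by 3.11. Tuba3a fell by 3.50, with near-identical tubulin genes elsewhere, which leaves its value uncertain. Slc13a5 lies on chromosome 11, and Pof1b and Pnma5 on the X chromosome.

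Among the other lists in ESCs, the cell cycle list was lower in KO. None of its 20 tested members passed alone (0 rose and 2 fell adjusted over the list alone, and 0 rose and 13 fell with the block), and its median was -0.55 (adjusted p = 0.00109, 0.594 as the adjusted p with an estimated correlation). Top2a, a cell cycle topoisomerase on chromosome 11 and the most abundant member that did not pass, stood at -1.02 (SE 0.24, adjusted p = 0.0729, and 0.0156 with the block). The hypoxia and glycolysis list had a median of -0.61 over 18 genes (adjusted p = 0.0182, 0.485 as the adjusted p with an estimated correlation). Its member Aldoa, a glycolytic aldolase, fell by 1.04 (adjusted p = 0.0436), and 0 rose and 2 fell adjusted over the list alone. The p53 targets and apoptosis list had a median of 0.39 over 18 genes (adjusted p = 0.0182, 0.485 as the adjusted p with an estimated correlation). Phlda3, a p53-induced repressor of Akt, rose by 1.17 (adjusted p = 0.0485) and the p53-induced nuclease Aen by 0.77 (adjusted p = 0.0416), while 3 rose and 0 fell adjusted over the list alone. The trophectoderm list had a median of 0.75 over 10 genes (adjusted p = 0.0182, 0.485 as the adjusted p with an estimated correlation). Its only called member was the keratin Krt8 (3 rose and 0 fell with the block, with Krt18 at 1.49 and an adjusted p of 0.0631, or 0.00842 with it), which rose by 2.40 (SE 0.33, adjusted p = 0.026), from 80.6 ± 16.6 to 456 ± 229, and 2 rose and 0 fell adjusted over the list alone. The mesodermal factor Twist1 rose by 2.16 (adjusted p = 0.0294) and the neural factor Olig2 fell by 1.30 (adjusted p = 0.0363). Pou5f1, which encodes the pluripotency factor Oct4, stood at -0.20 (adjusted p = 0.969), and at 0.02 without the replicate C libraries. Of the Pou5f1 exons, 14.1% lie over Gm19553 on the other strand, which leaves its values uncertain in every comparison. The naive pluripotency list had a median of -0.06 (adjusted p = 0.822).

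Of 15781 genes tested in ESCs, 376 passed, with 207 higher and 169 lower in KO. With replicate letter as a block the count was 4627 (2212 higher and 2415 lower), and without the replicate C libraries 8715 (4320 higher and 4395 lower). All 376 were called again, with the same sign, in both. Both fits reuse the same A and B libraries, so this is no independent support. A and B had r = 0.990 in each genotype, so without C the p values measure only the spread between near-alike libraries. With the block, the trophectoderm and p53 lists no longer passed (adjusted p = 0.127 and 0.0699), and without replicate C neither did trophectoderm (0.269) nor hypoxia and glycolysis (0.142). Leaving out any 1 of the ESC libraries labelled A or B, or any 1 EB library, gave 0 genes in limma, with 1943 to 2211 at an unadjusted p under 0.05. Leaving out replicate C of WT gave 1345 and of KO 2177. A fit on the 6 ESC libraries alone gave 0, with 1603 at an unadjusted p under 0.05. Leaving out 1 library ended list calls as follows, with adjusted p in parentheses: without WT ESC replicate C, germline (0.0547), trophectoderm (0.06), cell cycle (0.107) and hypoxia and glycolysis (0.524), and without WT ESC replicate B, trophectoderm (0.0558) and p53 targets and apoptosis (0.0888), and without KO ESC replicate C, trophectoderm (0.214) and p53 targets and apoptosis (0.158), and without WT ESC replicate A, p53 targets and apoptosis (0.0891). Over all alternatives, the adjusted p of these lists ran from 2.84e-05 to 0.555 for germline, 0.00642 to 0.765 for trophectoderm, 0.00121 to 0.765 for p53 targets and apoptosis, 2.84e-05 to 0.594 for cell cycle and 0.00115 to 0.671 for hypoxia and glycolysis. On all 10 libraries, edgeR called 339 and DESeq2 1959.

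The comparison of KO with WT EBs asks how loss of Mettl3 changes transcripts once the cells are led to differentiate. Genes of the endoderm were far lower in KO EBs. The laminin chain Lama1 (ENSMUSG00000032796, chromosome 17, 67697260 to 67822650, plus strand), a basement membrane protein made in bulk by parietal endoderm, stood at 38107 ± 574 normalized counts in WT EBs and 181 ± 7.13 in KO EBs (SD, n = 2), and fell by 7.71 on the log2 scale (SE 0.85, adjusted p = 0.00809). The endoderm factor Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354, minus strand) went from 1459 ± 333 to 10.7 ± 0.786 and fell by 6.94 (SE 1.09, adjusted p = 0.0287). Cubn, the endocytic receptor cubilin, fell by 8.36 (SE 0.77, adjusted p = 0.00506). Afp, alpha-fetoprotein, had no read in KO EBs and was at least 378-fold lower, taking 3 reads over the group as the floor. Of 18 endoderm genes tested, 0 rose and 9 fell, and 0 rose and 13 fell adjusted over the list alone. Their median was -5.05, with quartiles of -6.38 and -3.49 (adjusted p = 9.19e-19, and 0.00143 as the adjusted p with an estimated correlation, or 0.117 with the block as well). Chosen after their values were seen, the factors Gata4 and Gata6 fell by 4.84 and 5.26 (adjusted p = 0.00506 and 0.0356).

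Other genes with low values in KO EBs outside that list were the water channel Aqp8 and the calcium-binding S100g, which had no read there and were at least 1079.8-fold and 193-fold lower. Hkdc1, a hexokinase-like gene, fell by 7.97, Nxf7 fell by 7.67 and Cyp26a1, which breaks down retinoic acid, by 7.55. The matrix protein Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423180, minus strand), on chromosome 11, went from 28672 ± 981 to 1220.5 ± 37.8 and fell by 4.55 (adjusted p = 0.00343). It was the only one of 22 fibroblast and matrix genes to pass (0 rose and 3 fell with the block), with a list median of -0.51 (adjusted p = 0.131). Keratins Krt8 and Krt18, which pair in simple epithelia, fell by 4.34 and 3.50 (adjusted p = 0.00506 and 0.0101). They were the 2 called members of the trophectoderm list, with a median of -1.02 (adjusted p = 0.00986, 0.293 as the adjusted p with an estimated correlation) and 0 rose and 2 fell adjusted over the list alone. The receptor Pdgfra fell by 3.95 and the cardiac myosin Myh7 fell by 7.12, each the single call in the early mesoderm and cardiac muscle lists, neither of which passed (adjusted p = 0.113 and 0.163). Dkk1, a secreted Wnt inhibitor, had 2 reads in KO EBs, and its WT to KO ratio had a counting interval of 26.3 to 800.4.

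Imprinted genes were lower in KO EBs, with a median of -1.76 over 22 genes (adjusted p = 1.55e-04, 0.164 as the adjusted p with an estimated correlation). Over all genes 0 rose and 2 fell, and 0 rose and 10 fell adjusted over the list alone. The noncoding RNA Mirg of the Dlk1-Dio3 region fell by 3.37 (SE 0.31, adjusted p = 0.00506), from 671 ± 41.5 to 64 ± 6.42, and Sgce by 2.43 (adjusted p = 0.0204). Immediate early genes had a median of -1.19 (adjusted p = 1.55e-04, 0.164 as the adjusted p with an estimated correlation). Klf6 fell by 1.41 and Atf3 fell by 2.68 (adjusted p = 0.00959 and 0.0356), 2 of 11, and 0 rose and 3 fell adjusted over the list alone. The hypoxia and glycolysis list had a median of -1.14 (adjusted p = 1.55e-04, 0.164 as the adjusted p with an estimated correlation). P4ha1, a collagen prolyl hydroxylase subunit, fell by 2.85 (adjusted p = 0.0382), and 0 rose and 5 fell adjusted over the list alone of 18. The blood and endothelium list had a median of -0.88 (adjusted p = 0.0251, 0.164 as the adjusted p with an estimated correlation) and the cell cycle list -0.49 (adjusted p = 0.00986, 0.549 as the adjusted p with an estimated correlation), with no member called in either over all genes or adjusted over the list alone (0 rose and 3 fell with the block, and 1 rose and 9 fell with the block, in this order). Dazl fell by 2.27 (adjusted p = 0.0345), the p53 targets Btg2 and Ccng1 by 1.82 and 1.13, and the early response gene Ier3 by 2.05. Ccng1 lies on chromosome 11.

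Genes higher in KO EBs were fewer. The proteoglycan Cspg5 rose from 29.9 ± 3.28 to 479 ± 25.1 normalized counts, by 3.96 on the log2 scale (SE 0.43, adjusted p = 0.00759). Pof1b rose by 3.78, the caudal factor and Wnt target Cdx1 by 3.76, Ano9 by 3.44, the growth factor Pdgfc by 3.34, the testis poly(A) polymerase Papolb by 3.22, Ssc4d by 3.09 and Adgrb1 by 2.97. The naive pluripotency list had a median of 0.58 over 19 genes, with no member called (adjusted p = 0.0355, 0.431 as the adjusted p with an estimated correlation; 4 rose and 1 fell with the block). Pou5f1 stood at 0.38 (adjusted p = 0.984, 0.19 with the block and 0.0109 without replicate C). Hox genes had a median of 1.22 over 10 genes, with no member called (adjusted p = 0.0355, 0.631 as the adjusted p with an estimated correlation; 4 rose and 0 fell with the block).

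Over all genes, 290 passed in EBs, with 74 higher and 216 lower in KO. The shared spread includes that between ESC replicate C and A and B, so whether a gene passed in EBs also depended on the ESC libraries. With the block the count was 3578 (1463 higher and 2115 lower), and without the ESC replicate C libraries 8196 (3797 higher and 4399 lower). All 290 were called again, with the same sign, in both, which is no independent support, since the same EB libraries are reused. With the block, the naive pluripotency and trophectoderm lists no longer passed (adjusted p = 0.0804 and 0.0776), while endoderm did (8.90e-11, and 0.117 as the adjusted p with an estimated correlation). Without genes of chromosomes 10, 11, X and Y, a choice made after seeing the data, naive pluripotency (0.0553), cell cycle (0.0553) and Hox (0.086) did not pass. Without any 1 EB library, limma called 0 genes, with 1150 to 1178 at an unadjusted p under 0.05. Without 1 ESC library labelled A or B the count was 89 to 97, without WT ESC replicate C 997 and without KO ESC replicate C 1162. Leaving out 1 library ended list calls as follows, with adjusted p in parentheses: without WT EB replicate B, naive pluripotency (0.0629), and without KO EB replicate A, naive pluripotency (0.0589), and without KO EB replicate B, blood and endothelium (0.0622), and without WT EB replicate A, Hox (0.0594). Over all alternatives, the adjusted p of these lists ran from 0.006 to 0.649 for naive pluripotency, 0.00962 to 0.409 for blood and endothelium, 8.68e-04 to 0.586 for trophectoderm and 8.05e-04 to 0.631 for Hox. On all 10 libraries, edgeR called 281 and DESeq2 1552, and the 4 EB libraries fitted alone gave 7768.

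**Figure D2:**
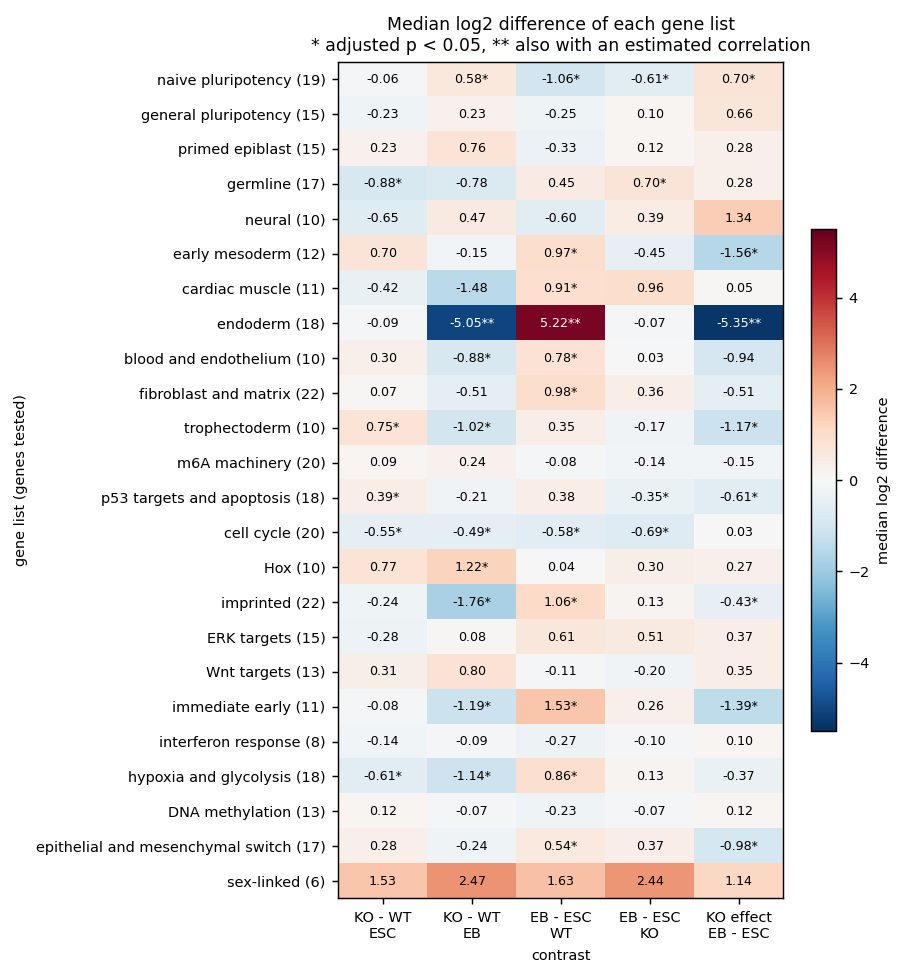
Median log2 difference of each of the 24 tested gene lists (vertical axis, with the number of genes tested) in the 5 contrasts (horizontal axis), coloured from blue (lower) to red (higher). The endoderm list had medians of -5.05 for KO against WT in EBs and 5.22 for EBs against ESCs in WT.

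The comparison of WT EBs with WT ESCs describes differentiation with Mettl3 present. Endoderm genes rose. Cubn rose by 9.59 on the log2 scale (SE 0.71, adjusted p = 0.00197), from 2.54 ± 1.55 (n = 3) to 2519 ± 259 (n = 2). Afp rose by 7.40 (adjusted p = 0.0442) and Sox17 by 6.59 (adjusted p = 0.0183). Foxa2, a pioneer factor of endoderm, had 3 reads in WT ESCs, and its EB to ESC ratio had a counting interval of 121 to 1720.1. Of 18 endoderm genes, 11 rose and 0 fell, and 15 rose and 0 fell adjusted over the list alone, with a median of 5.22 (adjusted p = 3.92e-17, and 0.00185 as the adjusted p with an estimated correlation, or 0.213 with the block as well). Gata4 and Gata6, chosen after their values were seen, rose by 5.24 and 5.20 (adjusted p = 0.0023 and 0.0215).

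Naive pluripotency genes were lower in WT EBs, with a median of -1.06 over 19 genes (adjusted p = 4.93e-07, 0.0929 as the adjusted p with an estimated correlation). Prdm14, a repressor that maintains the naive state, fell by 1.74 on the log2 scale (SE 0.20, adjusted p = 0.00791). It was the only member called over all genes (1 rose and 10 fell with the block), and 1 rose and 5 fell adjusted over the list alone. Immediate early genes had a median of 1.53 (adjusted p = 2.84e-04, 0.105 as the adjusted p with an estimated correlation), with Jun up by 2.91, Junb by 1.53 and Klf6 by 1.20 (7.52% of the Junb exons lie over Prdx2 on the other strand, which leaves its value uncertain), the 3 calls among 11 genes (6 rose and 0 fell adjusted over the list alone). The cell cycle list had a median of -0.58 (adjusted p = 2.00e-04, 0.401 as the adjusted p with an estimated correlation), and its member Mcm6, part of the replicative helicase, fell by 0.92 (0 rose and 4 fell adjusted over the list alone). The epithelial and mesenchymal switch list had a median of 0.54 (adjusted p = 0.00541, 0.0929 as the adjusted p with an estimated correlation). Its 2 called members were the keratins Krt8 and Krt18, which rose by 5.66 and 5.23 (3 rose and 0 fell adjusted over the list alone). The imprinted list had a median of 1.06 (adjusted p = 0.0436, 0.406 as the adjusted p with an estimated correlation), with H19 up by 4.73, Sgce by 2.53 and Mirg by 1.87 (4 rose and 1 fell adjusted over the list alone). Hypoxia and glycolysis genes had a median of 0.86 (adjusted p = 0.0147, 0.382 as the adjusted p with an estimated correlation), with P4ha1 up by 3.18 and Adm by 2.98 (2 rose and 0 fell adjusted over the list alone).

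Mesodermal and related lists also passed in WT EBs. The blood and endothelium list had a median of 0.78 with no member called (adjusted p = 0.00541, 0.0929 as the adjusted p with an estimated correlation; 2 rose and 0 fell adjusted over the list alone). Early mesoderm stood at 0.97 (adjusted p = 0.0147, 0.105 as the adjusted p with an estimated correlation), with Pdgfra up by 6.36 (2 rose and 0 fell adjusted over the list alone). Fibroblast and matrix genes stood at 0.98 (adjusted p = 0.0438, 0.654 as the adjusted p with an estimated correlation), with Sparc up by 2.17 (3 rose and 1 fell adjusted over the list alone), and at -0.14 without the replicate C libraries, in which this list was low. Cardiac muscle genes stood at 0.91 (adjusted p = 0.0499, 0.521 as the adjusted p with an estimated correlation). Myh7 rose by 6.71, and Myl3, a ventricular myosin light chain with 2 reads in WT ESCs, had an EB to ESC ratio with a counting interval of 337 to 1.01e4 (2 rose and 0 fell adjusted over the list alone). Of the Myl3 exons, 4.65% lie over Pth1r on the other strand, which also rose, so part of its EB counts is uncertain. Outside the lists, Hkdc1 rose by 8.20, Cyp26a1 by 8.11, the parathyroid hormone receptor Pth1r by 7.74 and Sema6d by 7.55. The stearoyl-CoA desaturases Scd1 and Scd2 fell by 3.24 and 2.64, Accsl by 3.38, Rpp25 by 2.23, Fam25c by 2.14, Capsl by 2.09, the mitochondrial superoxide dismutase Sod2 by 2.08 and Ccdc160 by 2.05. Uhrf1, which recruits the maintenance DNA methyltransferase, fell by 1.66, Olig2 by 1.75 and Igf2bp3 by 1.37, while the ERK phosphatase Dusp4 rose by 3.16 and Ier3 by 2.24.

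Over all genes, 392 passed between WT EBs and ESCs, with 317 higher and 75 lower in EBs. The count with the block was 5988 (3355 higher and 2633 lower), and without replicate C 7278 (3545 higher and 3733 lower). With the block the cardiac muscle, imprinted and hypoxia and glycolysis lists no longer passed (adjusted p = 0.281, 0.167 and 0.138). Without replicate C, cardiac muscle and fibroblast and matrix did not (0.471 and 0.802), and without genes of chromosomes 10, 11, X and Y, chosen after seeing the data, fibroblast and matrix did not either (0.182). The count was 5 without either WT EB library, 152 and 153 without KO EB replicates A and B, and 127, 114 and 720 without WT ESC replicates A, B and C. Without KO ESC replicates A, B and C it was 207, 198 and 1206. Leaving out 1 library ended list calls as follows, with adjusted p in parentheses: without WT ESC replicate B, early mesoderm (0.057), imprinted (0.109) and hypoxia and glycolysis (0.103), and without WT ESC replicate C, cardiac muscle (0.358) and fibroblast and matrix (0.529), and without KO ESC replicate B, cardiac muscle (0.0595), and without KO ESC replicate C, cardiac muscle (0.0948), and without WT EB replicate B, fibroblast and matrix (0.0514), and without WT ESC replicate A, imprinted (0.123) and hypoxia and glycolysis (0.0716). Over all alternatives, the adjusted p of these lists ran from 0.00242 to 0.391 for early mesoderm, 0.00799 to 0.721 for cardiac muscle, 0.0077 to 0.939 for fibroblast and matrix, 0.00187 to 0.406 for imprinted and 1.38e-05 to 0.721 for hypoxia and glycolysis. Quantile normalization moved the median of all genes from 0.09 to -0.09, and gave 416 higher and 231 lower.

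The same comparison in KO cells describes differentiation without Mettl3. Endoderm genes gave no call here without the block, and 1 rose and 2 fell with the block. Lama1, the most abundant member, stood at -2.41 (adjusted p = 0.217, 0.00704 with the block), and at -3.28 without replicate C (adjusted p = 5.14e-08). Their median was -0.07, or 0.23 with a gene at its bound, over 18 genes (adjusted p = 0.826; 0 rose and 0 fell adjusted over the list alone). Germline genes were higher in KO EBs, with a median of 0.70 over 17 genes (adjusted p = 0.00455, 0.897 as the adjusted p with an estimated correlation). Mael rose by 3.07 (SE 0.42, adjusted p = 0.0315), from 15.7 ± 8.27 (n = 3) to 129 ± 9.43 (n = 2), and 2 rose and 0 fell adjusted over the list alone. The cell cycle list had a median of -0.69 (adjusted p = 0.00129, 0.897 as the adjusted p with an estimated correlation) and p53 targets and apoptosis -0.35 (adjusted p = 0.0236, 0.897 as the adjusted p with an estimated correlation), with no member called in either (0 rose and 0 fell adjusted over the list alone, and 0 rose and 1 fell adjusted over the list alone). By the same order, 0 rose and 14 fell with the block, and 1 rose and 8 fell with the block. The naive pluripotency list had a median of -0.61 (adjusted p = 0.036, 0.897 as the adjusted p with an estimated correlation), with Dppa3, a maternal factor that shields methylated DNA, down by 2.00 (adjusted p = 0.0328; 0 rose and 1 fell adjusted over the list alone).

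Single genes that rose in KO EBs against KO ESCs were Cacng8 (4.20), Col6a4 (4.02), Tmem151b (3.79), Arhgef28 (3.69), the matrix protease Mmp9 (3.56), Cspg5 (3.53) and Stra8 (3.38), a retinoic acid target of premeiotic germ cells. Hspa1a stood at 3.58, but it has a near-identical neighbour, Hspa1b, and part of its exons lies over Gm20481 on the other strand, which leaves the value uncertain. Slc25a48 fell by 3.96, Scd1 by 3.16, Prag1 by 2.49, Scd2 by 2.46, while Ddah1 fell by 2.35, the adenylate kinase Ak4 by 2.29, Anapc10 by 2.10, Gsto1 by 2.08 and Uhrf1 by 1.54. In all, 127 genes passed, with 71 higher and 56 lower in EBs. In the blocked fit the count was 5988 (3081 higher and 2907 lower), and without replicate C 7465 (3363 higher and 4102 lower). Without replicate C the p53 and cell cycle lists did not pass (adjusted p = 0.153 and 0.0828), and without genes of chromosomes 10, 11, X and Y, chosen after seeing the data, the p53 list did not (0.08). With the block the naive pluripotency, germline and p53 lists no longer passed (adjusted p = 0.125, 0.087 and 0.087). Leaving out 1 library ended list calls as follows, with adjusted p in parentheses: without KO ESC replicate A, naive pluripotency (0.0928), germline (0.054) and p53 targets and apoptosis (0.054), and without KO ESC replicate B, naive pluripotency (0.0719), and without KO EB replicate B, naive pluripotency (0.0505), and without KO ESC replicate C, p53 targets and apoptosis (0.0625) and cell cycle (0.0611). Over all alternatives, the adjusted p of these lists ran from 0.00212 to 0.957 for naive pluripotency, 8.03e-05 to 0.897 for germline, 0.00237 to 0.957 for p53 targets and apoptosis and 2.37e-05 to 0.897 for cell cycle. Without any 1 ESC library labelled A or B, or any 1 EB library, limma called 0 genes, with 999 to 1893 at an unadjusted p under 0.05. Without replicate C of WT or of KO ESCs it called 919 and 947. The 5 KO libraries alone gave 0, with 1830 at an unadjusted p under 0.05, while edgeR called 193 and DESeq2 1419 on all 10 libraries.

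Whether the KO effect differed between EBs and ESCs was tested directly. Endoderm genes had a lower KO effect in EBs, with a median difference of -5.35 (adjusted p = 2.24e-19, and 0.0013 as the adjusted p with an estimated correlation, or 0.126 with the block as well; 0 rose and 5 fell, and 0 rose and 12 fell adjusted over the list alone). Lama1 had a mean of 1267 normalized counts in WT ESCs and 1269.8 in KO ESCs, and its KO effect in EBs minus that in ESCs was -7.41 (SE 1.09, adjusted p = 0.047). Dab2, an endocytic adaptor, had -6.45 (adjusted p = 0.0127). Krt8 was higher in KO ESCs and lower in KO EBs than in WT, with a difference of -6.74 (adjusted p = 0.00828), and Krt18 had -4.99. Olig2, lower in KO ESCs, had a difference of 2.36 (adjusted p = 0.0465), its neighbour Olig1 2.93, and Ndrg2 3.65 (adjusted p = 0.0399). Median differences of the other lists that passed were -1.17 for trophectoderm (adjusted p = 1.27e-04, 0.161 as the adjusted p with an estimated correlation) and -1.56 for early mesoderm (adjusted p = 7.23e-04, 0.086 as the adjusted p with an estimated correlation) and -0.61 for p53 targets and apoptosis (adjusted p = 7.23e-04, 0.2 as the adjusted p with an estimated correlation). They were -1.39 for immediate early (adjusted p = 7.23e-04, 0.161 as the adjusted p with an estimated correlation) and -0.98 for epithelial and mesenchymal switch (adjusted p = 0.00496, 0.105 as the adjusted p with an estimated correlation). They were 0.70 for naive pluripotency (adjusted p = 0.0183, 0.397 as the adjusted p with an estimated correlation) and -0.43 for imprinted (adjusted p = 0.0339, 0.397 as the adjusted p with an estimated correlation). In these lists the calls were Krt8 and Krt18, Btg2 (-2.62), Klf6 (-1.64) and Sgce (-3.56). With the block imprinted genes no longer passed (0.0733), and without replicate C neither imprinted (0.119) nor naive pluripotency genes did (0.208). Leaving out 1 library ended list calls as follows, with adjusted p in parentheses: without WT ESC replicate C, naive pluripotency (0.22), and without KO ESC replicate C, naive pluripotency (0.15), imprinted (0.289) and immediate early (0.108), and without WT ESC replicate A, imprinted (0.0883), and without WT ESC replicate B, imprinted (0.0816). Over all alternatives, the adjusted p of these lists ran from 0.00413 to 0.614 for naive pluripotency, 0.00466 to 0.397 for imprinted and 6.20e-05 to 0.409 for immediate early.

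Over all genes, 75 passed for this difference, with 10 higher and 65 lower. A block brought the count to 1230 (443 higher and 787 lower), and without replicate C 5703 (2568 higher and 3135 lower). Without any 1 EB library, limma called 0 genes, with 765 to 798 at an unadjusted p under 0.05. Without WT ESC replicates A, B and C the count was 10, 15 and 333, and without those of KO 3, 15 and 497. On all 10 libraries, edgeR called 84 and DESeq2 774.

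Lists that passed in no contrast are given as KO against WT medians in ESCs and then EBs. They were -0.23 and 0.23 for general pluripotency (15 genes tested), 0.23 and 0.76 for primed epiblast (15), -0.65 and 0.47 for neural (10), and -0.28 and 0.08 for ERK targets (15). Wnt targets had 0.31 and 0.80 (13), interferon response -0.14 and -0.09 (8), DNA methylation 0.12 and -0.07 (13), and sex-linked genes 1.53 and 2.47 (6). The 2-cell-like list had 4 genes tested, too few for a list test, with medians of -2.54 and 0.13 and no call.

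KO effects in ESCs and EBs, which share no library, had Pearson r = 0.34 and Spearman rho = 0.39 across 15781 genes. Both comparisons called 24 genes higher, where independent lists would share 0.971, and 15 lower, where independent lists would share 2.31, while 6 went opposite ways. Both use 1 variance per gene from the same fit, so calls can overlap more than independent lists without a shared effect. A difference between the WT and KO lines that ESCs and EBs share cannot be parted here from a shared effect of Mettl3. Changes from ESCs to EBs in WT and in KO had Pearson r = 0.56 and Spearman rho = 0.59, and 0.38 and 0.34 without replicate C. Both called 12 genes higher (1.43 for independent lists) and 10 lower (0.266), while 2 went opposite ways. Differences of KO from WT taken pair by pair had r = 0.918 between ESC letters A and B across genes, 0.934 between the EB letters, 0.232 and 0.227 between ESC C and ESC A and B, and 0.0910 to 0.0938 between ESC C and the EBs.

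By chromosome, protein-coding genes of chromosome 11 (800 genes) had a median KO minus WT difference below that of the other autosomes by the following amounts. The shift was -0.39 in each of ESC replicates A and B, -0.48 and -0.49 in EB replicates A and B, and -0.04 in ESC replicate C. Other autosomes lay between -0.07 and 0.11 in ESC replicate A, -0.10 and 0.11 in ESC replicate B, -0.03 and 0.09 in EB replicate A and -0.03 and 0.10 in EB replicate B. In the replicate C pair chromosome 10 stood at -0.39, chromosome 17 at -0.12, and the highest autosome at 0.09. The X chromosome (286 genes) was below the autosomes in every pair, at -0.12, -0.16 and -0.27 in ESC replicates A, B and C and -0.16 and -0.14 in EB replicates A and B.

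**Figure D3:**
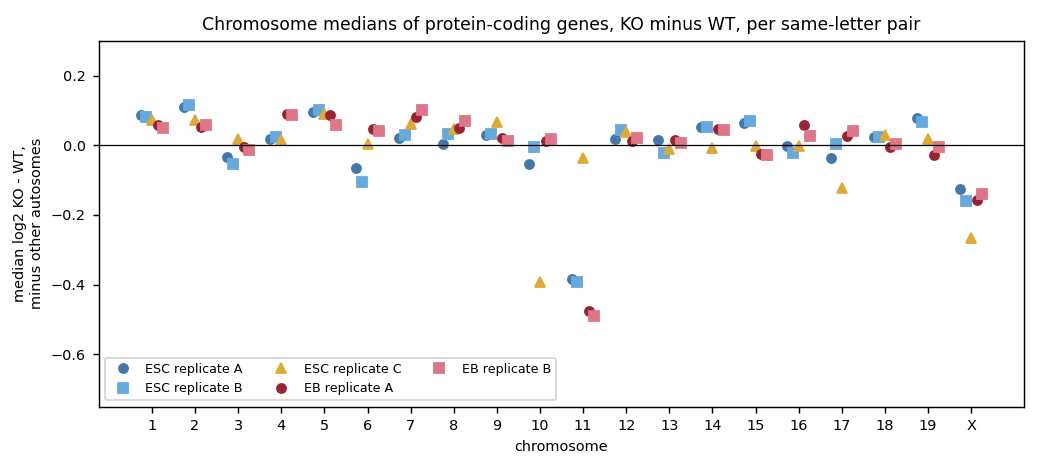
Median log2 difference of KO from WT of the protein-coding genes of each chromosome (horizontal axis), minus the median of the other autosomes (vertical axis), with a point per same-letter pair of libraries. Chromosome 11 lay at -0.39 in ESC replicates A and B and at -0.48 and -0.49 in the EBs, and chromosome 10 at -0.39 in ESC replicate C.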

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

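The tests of MEK inhibition, of a Mettl3 effect on chromosome 11 and of the endoderm genes were chosen only after the results were seen. The KO effect differed between EBs and ESCs, by a test of the difference itself, for 75 genes (0 in limma without any 1 EB library, with 765 to 798 at an unadjusted p under 0.05, and 3 to 497 without 1 ESC library; 84 in edgeR and 774 in DESeq2). Log2 differences (effect in EBs minus effect in ESCs) were 4.23 for Cspg5, 4.08 for Stra8, 3.65 for Ndrg2, 3.19 for Nptx2, 2.93 for Olig1, 2.36 for Olig2 and 2.26 for Sema5b. Adgre5 had 2.20, with 23.8% of its exons over Ddx39 on the other strand. On the lower side they were -8.98 for Cubn, -7.41 for Nxf7, -7.41 for Lama1 and -6.74 for Krt8. Trpc5os had -7.33 with 3 reads in KO EBs, and its WT to KO ratio in EBs had a counting interval of 53.6 to 768. Aqp8 had -10.16 with no read in KO EBs, and Slc34a2 and Frzb had -7.86 and -7.70 with no read in WT ESCs, so these fitted values depend on the pseudocount. Lists whose effect differed, by adjusted p, were endoderm (2.24e-19), trophectoderm (1.27e-04), early mesoderm, p53 targets and apoptosis and immediate early (each 7.23e-04), and the epithelial and mesenchymal switch (0.00496). Naive pluripotency (0.0183) and imprinted genes (0.0339) followed. With an estimated correlation only endoderm passed (0.0013, but 0.126 with the block), the others lying at 0.086 to 0.397.

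The 6 ESC libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 376 genes and was the only 1 to reach that count, and the highest of the others gave 2. Among the 4 splits that part all 3 pairs, the block gave 4627 for the real one and 2, 0 and 0 for the others.

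ESC replicate C stood apart from A and B in both genotypes. Its lower depth is argued against, since WT replicate A thinned to the reads of replicate C still had r = 0.979 with replicate B, where C had r = 0.692. A library preparation that kept less RNA without a poly(A) tail stays open, and the prediction made for it before the result was seen was met. Histone genes had a median of -6.91 or lower in C relative to A and B, taking 3 reads as the floor in C. The noncoding RNA Rn7sk had 0 and 5.55 normalized counts in C of WT and KO ESCs. Its means over A and B were 104159 and 195130.5, and its means in WT and KO EBs 94508 and 208376. The labels name poly(A) RNA, which these counts outside C do not bear out. Growth without the effect of the MEK inhibitor also stays open, with ERK targets at 1.74. These may act together, and the cells behind C also differed from those behind A and B in sex-linked genes. Y-linked genes had 0 and 1 reads in C, where A and B had 353 to 3369. X-linked protein-coding genes had medians of 1.18 and 1.05 in C relative to A and B in WT and KO. Autosomal ones had 0.06 and 0.04. What part of the wider difference a difference between cell lines accounts for was not tested.

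Genes of chromosome 11 were lower in KO than in WT in ESC replicates A and B and in EBs. The shift in the replicate C pair was 9.60% of that in A and B. This cannot decide whether Mettl3 loss affects the chromosome in every line. The value rests on the replicate C pair alone, and those libraries stood apart from A and B in other ways. A difference in copy number of the whole chromosome between the lines stays open as a candidate explanation. In each of 10 groups of genes along the chromosome the median was below the other autosomes, in ESC replicates A and B and in EBs. Chromosome 11 genes of C relative to A and B lay at -0.29 in WT and 0.04 in KO, each relative to the other autosomes. Measured against C, WT A and B thus stood higher and KO A and B did not. Replicate C also differed from A and B on other chromosomes in both genotypes, with chromosome 13 at -0.12 in WT and -0.18 in KO. It therefore cannot settle in which genotype the difference lies.

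Endoderm genes were far lower in KO than in WT EBs. A difference in the levels of these genes already present in ESCs is argued against, since the list's median in ESC replicates A and B was -2.12% of that in EBs. Some members were low there in both genotypes, such as Ttr at 4.41 in WT and 4.90 in KO and Gata6 at 22.2 and 17.8. The test therefore cannot tell whether WT and KO ESCs already differed in their capacity to form endoderm. A lower share of endoderm-like cells in KO EBs may account for it. The upper quartile of -3.49 over the list and the 17 of 18 genes below -1 restate the fall itself. They cannot part fewer such cells from lower expression per cell. A slower loss of the ESC state stays open, with the naive pluripotency list at a median of 0.58 in KO relative to WT EBs (adjusted p = 0.431 with an estimated correlation). That list stood at 0.23 already in ESC replicates A and B, and without replicate C its difference of effects was 0.16 (adjusted p = 0.208), so part of the EB value may have been present in ESCs. The labels do not say how many lines the libraries of a genotype come from, so a difference between the WT and KO lines other than Mettl3 stays open. The libraries did differ in other ways. Y-linked genes of the sex-linked list summed to 253 and 333 normalized counts in WT and 1833 and 2103 in KO ESC replicates A and B, and to 219.9 and 277 in WT and 1595 and 1957 in KO EBs, beside the shift of -0.39 on chromosome 11. Whether such differences bear on the endoderm genes was not tested.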

How the results depend on the processing

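Leaving out genes of chromosomes 10, 11, X and Y, joining the block with the loss of replicate C, and joining either with an estimated correlation, were chosen after seeing the data. Counts of called genes depended on the setting. The median of the fibroblast and matrix list in WT EBs against ESCs turned from 0.98 to -0.14 without replicate C, and single genes that did not pass also changed sign without it. With the replicate block there were 4627 in KO against WT ESCs, 3578 in KO against WT EBs, 5988 in WT EBs against ESCs, 5988 in KO EBs against ESCs and 1230 for the difference of effects. Without both replicate C libraries there were 8715 in KO against WT ESCs, 8196 in KO against WT EBs, 7278 in WT EBs against ESCs, 7465 in KO EBs against ESCs and 5703 for the difference of effects, and with the block as well 11159 in KO against WT ESCs, 10695 in KO against WT EBs, 10188 in WT EBs against ESCs, 10303 in KO EBs against ESCs and 9084 for the difference of effects. DESeq2 gave 1959 in KO against WT ESCs, 1552 in KO against WT EBs, 1525 in WT EBs against ESCs, 1419 in KO EBs against ESCs and 774 for the difference of effects. Single libraries left out gave 0 to 2177 for KO against WT ESCs, 0 to 1162 for KO against WT EBs, 5 to 1206 for WT EBs against ESCs, 0 to 947 for KO EBs against ESCs and 0 to 497 for the difference of effects. The highest values came from leaving out replicate C of KO ESCs and the lowest from leaving out an EB library, or equally, for KO against WT ESCs and KO EBs against ESCs, an ESC library labelled A or B. Where this left an EB group with 1 library, that library is assumed to vary like the other groups. Fits on only the groups of a contrast gave 0, 7768, 60 and 0 in the order above, with 1603 and 1830 at an unadjusted p under 0.05 where limma gave 0. Without a filter there were 45, 1351 and 1655 in the first 3 contrasts. Quantile normalization gave 732 for KO EBs against WT, 647 for WT EBs against ESCs, 459 for KO EBs against ESCs and 173 for the difference of effects, and the share of higher genes went from 25.5% to 41.7% in the first of these. A pseudocount of 8 gave 439, 249 and 191 for KO against WT EBs, KO EBs against ESCs and the difference of effects, and 0.25 gave 46 for the last. For KO EBs against ESCs, eBayes without trend or robust variances gave 231 and edgeR 193. In all, 87 of 120 counts moved by over 1.5 times and 33 did not. In simulated data, the shift of replicate C cut recovery of changes of 1 in ESCs from 93% to 11%, and with the block it was 72%. Apart from this, why counts moved was not tested.

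Pou5f1 in KO against WT ESCs stood at -0.20 and turned to 0.0419 with quantile normalization, 0.357 without WT ESC replicate C, 0.0138 without KO ESC replicate B and 0.0155 without both replicate C libraries, with or without the block. It was -0.54 without KO ESC replicate C. The adjusted p was 0.549 or more in each of the 5 fits with the other sign. The 158 results for named genes include some, such as Pou5f1, that had no call to lose. Of the 158, 0 lost their call with the block, 0 without both replicate C libraries, 2 with DESeq2, 17 with edgeR and 25 without a filter. Without a single EB library or ESC library labelled A or B, 96 to 146 lost it. Fits on only the groups of a contrast lost 75, a pseudocount of 0.25 lost 21, quantile normalization 17, eBayes without trend or robust variances 13, and a mean of 50 or more 10 of 146. Recomputed size factors changed no named call. Of the 37 list calls, the 3 of the endoderm list passed under each alternative that changed 1 choice, with adjusted p of at most 0.00185. With an estimated correlation and the block together they did not pass, at 0.117 in KO against WT EBs, 0.213 in WT EBs against ESCs and 0.126 for the difference of effects. With an estimated correlation and without replicate C they stood at 0.0392, 0.0276 and 0.0631. The other 34 were lost with an estimated correlation. Of the 37, the block ended 11, no filter 10, quantile normalization 9, the loss of both replicate C libraries 8, and that loss joined with the block 7. Leaving out genes of chromosomes 10, 11, X and Y ended 5, a pseudocount of 0.25 ended 3, a mean of 50 or more 2 of 32, and recomputed size factors and fits on only the groups of a contrast 1 each. Single libraries left out ended 1 to 8. Depth limits the replicate C libraries, where 3 reads stand at 8.33 to 9.88 normalized counts.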

Other observations

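The genes in this part were chosen after their values were seen. Among imprinted genes, the maternally expressed RNA H19 stood at 9731 ± 726 normalized counts in WT EBs and 271 ± 47.7 in KO EBs (SD, n = 2), a log2 difference of -5.17 (SE 1.01, adjusted p = 0.0516, 0.0385 with the block and 6.12e-08 without replicate C). Its ESC values differed by replicate, with 598, 524 and 155 in WT replicates A, B and C, and 377, 331 and 2486 in KO. Meg3 and Rian, maternally expressed RNAs of the Dlk1-Dio3 region like Mirg, stood at 1807 ± 50.9 and 3429 ± 318 in WT EBs and at 195 ± 8.45 and 259.5 ± 12.4 in KO EBs. They were lower in KO in every ESC pair too. Meg3 had 377, 340.4 and 849.9 in WT ESC replicates A, B and C and 106, 97.2 and 492 in KO, and Rian 769, 875 and 1799 in WT and 143, 153 and 1244 in KO. Their log2 differences in EBs were -3.20 and -3.72 (adjusted p = 0.0935 and 0.118, 0.00437 and 0.0105 with the block). Igf2 stood at 92.6 ± 25.1 in WT EBs and 16.6 ± 5.48 in KO EBs.

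Esrrb and Klf4, factors of the naive state, differed between genotypes in opposite directions in ESC replicates A and B and in C. Esrrb stood at 3875 and 3618 in WT ESC replicates A and B and at 8803 and 8049.9 in KO, but at 8027 in WT and 4585 in KO replicate C. Klf4 stood at 2361 and 2108 against 5434 and 4617 in A and B, and at 3050.2 against 1708 in C. Nanog did not share this, with 3279, 3834 and 7777 in WT and 3386, 3768 and 6079.7 in KO replicates A, B and C. Over the 3 pairs neither Esrrb nor Klf4 passed (log2 0.51 and 0.50, adjusted p = 0.576 and 0.672), and without replicate C both did (1.17 and 1.17, adjusted p = 6.14e-06 and 1.78e-04). In EBs, Esrrb stood at 2172 ± 29.9 in WT and 4493 ± 133 in KO.

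Sex-linked transcripts also differed by library. The 4 Y-linked genes of the sex-linked list had 0 reads in WT and 1 read in KO ESC replicate C. In sum they reached 253 and 333 normalized counts in WT ESC replicates A and B, 1833 and 2103 in KO ESC replicates A and B, 219.9 and 277 in WT EBs, and 1595 and 1957 in KO EBs. X-linked protein-coding genes (286) had a median of 1.18 in replicate C relative to A and B in WT and 1.05 in KO, against 0.06 and 0.04 for autosomal ones (9019). Xist was at 41.7 to 148 normalized counts over the ESC libraries and 97.3 to 141 over the EB libraries. Chromosome 11 genes of replicate C relative to A and B lay at -0.29 in WT and 0.04 in KO, and chromosome 10 genes at 0.03 in WT and -0.34 in KO, each relative to the other autosomes.

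Processed pseudogenes and small nucleolar RNAs were low in replicate C, and ribosomal protein genes high. With genes under 3 reads in C at 3 reads, processed pseudogenes (713) had a median of -2.99 relative to A and B in WT and -2.98 in KO, and small nucleolar RNAs (97) -2.07 and -2.02. These are bounds, since 508 and 521 of the pseudogenes and 71 and 67 of the small nucleolar RNAs had no read in C. Ribosomal protein genes (79) had 3.91 and 3.65. Rmrp, the RNA of a mitochondrial processing enzyme, had no read in replicate C and means of 121456 and 122209 normalized counts over A and B of WT and KO ESCs. Malat1 was 66.4-fold lower in C in WT and 153-fold lower in KO. Spry4, a feedback inhibitor of ERK signalling, had 2447 and 1897 normalized counts in replicate C of WT and KO, and at most 1.82 in A and B.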
